A study of Mus musculus with 16 samples.

How the data were processed

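Messenger RNA from interscapular brown adipose tissue of C57BL/6J mice was measured by strand-marking mRNA sequencing with 75 bp single reads, per the labels. The 16 libraries fell into 4 groups of 4 by genotype (wild type, WT, or Ucp1 knockout, KO) and treatment (saline or isoproterenol, infused by minipump for 3 days). Groups were read from the genotype and treatment labels and replicate numbers from the sample titles. In 3 KO saline libraries the column header of the values carries another replicate number than the title, and the titles were used. The treatment text attached to the saline samples describes the isoproterenol infusion, while their treatment characteristic says saline, and the characteristic was used.

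The deposited values are log2 counts per 1e6 reads (log2 CPM), 1 per Ensembl gene and library, for the same 15350 genes in every library. The submitters' processing notes name the aligner STAR, the R package limma and the mouse genome build mm39. Their versions, the annotation, the read counter, its strand setting and the rule by which genes were left out before deposit are not given in the sources used here. Each deposited log2 value, taken as a power of 2, was a whole number of reads plus 0.5, times a step set by its library, which is the form that limma's voom transform with a prior count of 0.5 gives. Whole reads were recovered from 100% of the values, all within 1e-06 of a whole number. The recovered reads gave the depth of each library, from 9004515 to 20986735 reads over the listed genes. The library size behind the deposited CPM was 0.854 to 1.25 times that total, so the authors had applied scaling factors before the log2 transform. A CPM printed here contains the prior count, so a gene with 0 reads has a small CPM above 0. One read was worth 0.0476 to 0.115 CPM, and 3 reads, the floor used here, 0.143 to 0.345 CPM. Depth therefore limits genes of a few reads per library. Such limits cover counting error alone.

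Gene symbols came from the GENCODE M21 annotation, which is of another build than the reads and was used for names, chromosomes, gene order, GC content and transcript length, never for coordinates. A symbol was found for 15320 gene identifiers and not for 30, and 6 identifiers shared a symbol. Genes with near-identical copies, pseudogenes and overlapping genes are uncertain, since the counter and its treatment of shared reads are not known. No mitochondrially encoded gene was among the 15350, so that list is not analysed here.

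The comparisons, tests, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined. A count model had been planned for whole-number counts. Because the values held were log2 CPM, the planned fallback was used, a linear model in limma 3.58.1 (R 4.3.3, statmod 1.5.0) fitted directly to the deposited log2 values without a further pseudocount. The model had 4 group means over all 16 libraries (12 residual degrees of freedom) and empirical Bayes moderation with a mean-variance trend and robust hyperparameters. The 5 contrasts were isoproterenol against saline in WT and in KO, KO against WT under saline and under isoproterenol, and the difference of the 2 isoproterenol responses (KO response minus WT response, the interaction). P-values were adjusted over the 15350 genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. A fold change is a difference of log2 means with its standard error (SE), and levels are mean CPM with the standard deviation (SD) of 4 libraries. The labels do not say whether the libraries of a group came from separate animals. P-values therefore measure the spread between these samples, which may be technical.

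Ucp1 and Gdf10 were also compared in each pair of groups by an exact two-sided permutation test of log2 CPM over the 70 arrangements of 4 against 4 libraries, with Benjamini-Hochberg adjustment over the 8 comparisons. The smallest p this test can give is 0.0286. The arrangements treat all libraries as unpaired.

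Gene lists numbered 35, for metabolism, stress, immune and secreted-factor genes and for markers of cell types the tissue could hold. Lists with at least 5 measured genes (33 lists, 687 different genes in all) were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists within a contrast. Each was tested again with a correlation estimated from the data, where no list in any contrast had an adjusted p under 0.05, and with limma's fry, which asks whether a list's genes move on balance in 1 direction and does not compare the list with other genes. Counts of called members are given over all genes and adjusted over the list alone. Keratinocyte markers had 4 measured genes and were not tested. List scores per library are means of the members' log2 CPM after centring each gene on its mean over the 16 libraries.

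Genes named in the text are, per contrast, the 8 called genes with the largest positive and the 8 with the largest negative log2 fold change among those with a mean of at least 5 CPM in a compared group and a symbol that is not a clone or predicted name. For the contrasts of 2 groups all 4 libraries of 1 group had to lie above all 4 of the other. Members of the fixed lists, mostly the 4 with the smallest adjusted p in a contrast, were named too, and Ucp1 and Gdf10 in every contrast.

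The whole pipeline was tested on simulated data drawn for the 15350 real genes, with 200 genes changed in WT isoproterenol, 50 at each fold. In the WT isoproterenol contrast 14% of genes changed 1.5-fold were recovered, 48% at 2-fold, 70% at 4-fold and 90% at 8-fold. For the interaction the shares were 12%, 30%, 54% and 86%. False calls made up 6 of 131 called genes in the WT contrast. A list of 30 simulated genes changed together was recovered and 0 of the 33 other lists were called. The simulated noise was independent between genes and had 1 spread per gene for all 4 groups. These results therefore do not cover lists of correlated genes or the wider spread of the real KO isoproterenol group.

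Alternatives to the settings were other size factors, voom weights, a filter of 1 CPM in 4 libraries, other pseudocounts, a fit of the 2 compared groups alone, the replicate number as a block, and leaving out each library. Added after the data were seen were scaling by library totals, 1 variance weight per group, a skeletal muscle score as a covariate, centring over bins of GC content and length, the block by header numbers, a replicate block for the WT libraries alone and the list tests without 1 library. Their effects are in the closing section. Same-numbered libraries of WT saline and WT isoproterenol deviated together from their group means in all 4 pairs (correlation 0.21 to 0.54), so for that comparison the number was taken to pair the samples, a pairing that comes from the data and not from the labels. Skeletal muscle scores ran in the same order, at 0.73, -3.46, 2.42 and 5.37 in WT saline replicates 1 to 4 and -0.37, -3.80, 2.17 and 3.55 in WT isoproterenol. How much of these correlations comes from muscle genes was not tested. In the 5 other pairs of groups at least 1 of 4 correlations was under 0.1. All per-sample columns held were used.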

Results

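Brown adipose tissue makes heat through UCP1, a protein of the inner mitochondrial membrane that uncouples respiration from ATP synthesis. Transcripts of interscapular brown adipose tissue were measured in WT and Ucp1-KO mice after 3 days of saline or of isoproterenol, an agonist of beta-adrenergic receptors infused at 60 mg per kg per day. Each of the 4 groups held 4 libraries, and 15350 genes had a value in each library. Recovered reads numbered 10479767 to 12241512 per library in WT saline, 11093784 to 16720338 in WT isoproterenol, 9004515 to 14381797 in KO saline and 12914590 to 20986735 in KO isoproterenol. The first principal component of log2 CPM held 50.3% of the variance and the second 12.9%. KO isoproterenol libraries lay at 57.5 to 176 on the first component, and the 12 other libraries lay between -62.0 and 3.97. Correlations between libraries of 1 group ran from 0.949 to 0.977 in WT saline, 0.958 to 0.985 in WT isoproterenol, 0.964 to 0.974 in KO saline and 0.852 to 0.957 in KO isoproterenol. KO isoproterenol replicate 1 stood apart from the other 3 libraries of its group, at 176 on the first component against 57.5, 100 and 107.

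**Figure D1:**
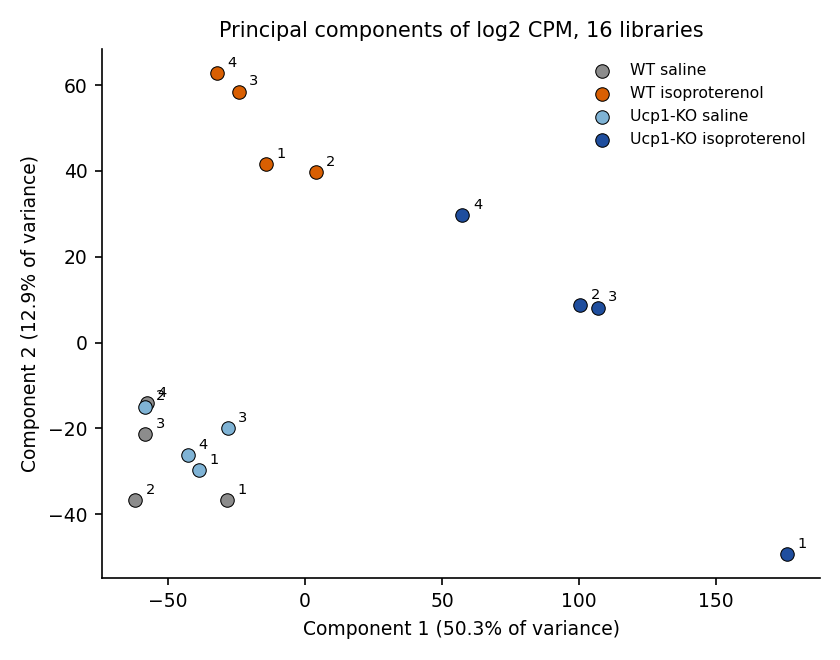
First (50.3% of variance) and second (12.9%) principal components of the deposited log2 CPM values, 1 point per library, coloured by group and numbered by replicate. The 4 KO isoproterenol libraries lie at 57.5 to 176 on the first component, replicate 1 farthest from the rest.

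Ucp1 (ENSMUSG00000031710, chromosome 8), the targeted gene, was read in every library first. Its level in WT saline was 3076 ± 527 CPM (SD, n = 4; 2298 to 3449 per library) and in WT isoproterenol 14170 ± 4638 CPM (n = 4; 8905 to 18458). KO saline libraries held 1118, 588, 1156 and 410 CPM in replicates 1 to 4, all below the 4 WT saline libraries. KO isoproterenol libraries held 19.0, 268, 848 and 2129 CPM in replicates 1 to 4, all below the 4 WT isoproterenol libraries. The labels do not say which part of Ucp1 was deleted, and a value per gene can hold reads from outside that part, so the remaining KO reads check nothing about the genotype. KO minus WT was -2.02 on the log2 scale under saline (SE 0.98, limma adjusted p = 0.742) and -5.45 under isoproterenol (SE 0.98, limma adjusted p = 5.28e-04). Isoproterenol minus saline was 2.16 in WT (limma adjusted p = 0.152) and -1.27 in KO (limma adjusted p = 0.303). The 2 isoproterenol differences were -3.43 apart (SE 1.39, limma adjusted p = 0.0826). In an exact two-sided permutation test the WT isoproterenol difference and both KO against WT differences had p = 0.0286, the smallest 4 against 4 libraries can give (adjusted p = 0.0571), and the KO isoproterenol difference had p = 0.514. The WT difference was called when the 8 WT libraries were fitted alone (limma adjusted p = 1.18e-04), and the saline difference when its 8 libraries were (limma adjusted p = 0.0438). With KO isoproterenol replicate 1 left out, the KO difference was 0.0717 (limma adjusted p = 0.927) and the interaction -2.09 (limma adjusted p = 0.0514). Without KO isoproterenol replicate 4 the interaction was called at -4.36 (limma adjusted p = 0.0102) and KO Ucp1 fell by 2.20 on the log2 scale after isoproterenol (limma adjusted p = 0.0442).

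Isoproterenol in WT tissue raised cell cycle genes and neutrophil markers, and the largest increases among the named genes were those of Elovl3 and Mfsd2a. Elovl3, an elongase of very long chain fatty acids that cold induces in brown fat, rose from 4.16 ± 2.67 to 600 ± 266 CPM (SD, n = 4; log2 fold change 7.44, SE 1.25). Mfsd2a, a transporter of lysophosphatidylcholine, rose by 7.38 on the log2 scale from 0.386 to 78.6 CPM, and Bmp8b, a ligand of the BMP family made by brown adipocytes, rose from 4 to 561 reads over the 4 libraries of each group. Lep, which encodes the fat-mass hormone leptin, fell from 98.9 to 7.70 CPM (log2 fold change -4.12, SE 0.69), and Impdh1, an enzyme of guanine nucleotide synthesis, from 1665 to 124 CPM (-3.75, SE 0.27). Also higher were the acute-phase gene Orm2 (6 reads in WT saline and 532 after isoproterenol), the secreted phospholipase Pla2g2e (10 and 653), Cpne5 (5 and 391, not called with the WT replicate block, limma adjusted p = 0.0528), the linker histone gene Hist1h1d (log2 fold change 5.01) and the transferrin receptor Tfr2 (4.78). Also lower were Shisa7 (-4.54), Cdsn (-4.32), Strip2 (-4.26), the noncoding host gene Snhg11 (-3.97), the matrix gene Fras1 (-3.84) and Rab17 (-3.69).

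Cell cycle genes rose together in WT, with 22 of 28 higher and 0 lower (26 adjusted over the list alone, median log2 fold change 2.09). Examples were thymidylate synthase Tyms (1.44), the mitotic genes Cdc20 (2.93) and Ccnb2 (2.81) and the replication licensing gene Mcm7 (0.78). The list was called by camera (adjusted p = 1.37e-13), with adjusted p = 0.950 with an estimated correlation. Neutrophil markers had 4 of 8 higher and 0 lower (6 adjusted over the list alone, camera adjusted p = 1.53e-04, adjusted p = 0.586 with an estimated correlation), among them Lcn2 (3.43) and the calprotectin subunits S100a8 (2.05) and S100a9 (1.87). Extracellular matrix genes had 5 of 27 higher and 0 lower (7 adjusted over the list alone, camera adjusted p = 0.00112, adjusted p = 0.950 with an estimated correlation), with Timp1 at 2.88, Loxl1 at 2.16 and elastin Eln at 1.89. Of the macrophage markers 3 of 20 were higher, Mrc1 (1.42), Cd68 (1.45) and the complement gene C1qc (1.04), and 3 adjusted over the list alone (camera adjusted p = 0.00824, adjusted p = 0.950 with an estimated correlation). With 1 library left out the macrophage count was 4 without WT saline replicate 1, 1 without WT saline replicate 4 or WT isoproterenol replicate 4, and 0 without any of the other 5. Scaled by library totals it was 0, as it was with the WT replicate number as a block (Mrc1 adjusted p = 0.0647, Cd68 0.0662, C1qc 0.0847), and it was 9 when the 8 WT libraries were fitted alone. Proteasome genes had 4 of 28 higher (4 adjusted over the list alone, camera adjusted p = 0.00322), and 1 with library totals.

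Glycolysis genes had 4 of 22 higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.0159), with lactate dehydrogenase Ldha at 1.41 and Pfkp at 1.30. Fatty acid uptake and oxidation genes had 3 of 32 higher, Acsl5 (2.10), Fabp5 (1.41) and the lipoprotein lipase Lpl (1.34), and 1 adjusted over the list alone (camera adjusted p = 0.0251). Of these, 2 were called without WT saline replicate 1 or WT isoproterenol replicate 3, and 1 without any other 1 of the 8 libraries. Lpl was not called with the WT replicate block (limma adjusted p = 0.105). Cholesterol synthesis genes had 4 of 22 higher and 1 lower, Fdft1 at -1.96 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0283), and 2 higher without any 1 of the 8 libraries or with the WT replicate block. For these 3 lists and the proteasome, adjusted p = 0.950 with an estimated correlation. The thermogenic programme had 3 of 29 higher, Elovl3, Bmp8b and the glycerol kinase Gk (2.56), 3 adjusted over the list alone, and was not called as a list (camera adjusted p = 0.0715). Its scores did not overlap, at 0.33 to 1.02 in WT isoproterenol and -0.50 to 0.07 in WT saline. The deiodinase Dio2 was at 2.65 (limma adjusted p = 0.0548). No respiratory chain gene of 44, no tricarboxylic acid (TCA) cycle gene of 17 and no interferon gene of 28 was called, over all genes or adjusted over the list alone, with medians of 0.25, 0.19 and 0.01 and camera adjusted p of 0.146, 0.480 and 0.769. In limma's test 0, 0 and 3 of these genes had an unadjusted p under 0.05.

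Over all genes, 2546 of 15350 were called in WT, 1167 higher and 1379 lower (limma, Benjamini-Hochberg), and 592 and 561 of them by at least 2-fold. The count was 4923 when the 8 WT libraries were fitted without the KO libraries, where most lists named here gained calls as well. In that fit 17 of 32 fatty acid oxidation genes were higher and 0 lower, 10 and 1 of 22 glycolysis genes, 9 and 3 of 29 thermogenic genes, 11 and 1 of 44 respiratory chain genes, and 5 and 1 of 17 TCA cycle genes. The counts were 12 and 2 of 27 extracellular matrix genes, 11 and 0 of 28 proteasome genes, 8 and 1 of 22 cholesterol genes and 3 and 2 of 28 interferon genes. The count of all genes was 1623 without WT saline replicate 2 and 1672 without WT saline replicate 3. Library totals, which moved the median of all genes by -0.11 in WT, gave 770 higher and 1748 lower.

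Isoproterenol in KO tissue lowered genes of mitochondrial respiration and lipid synthesis and raised genes of macrophages, neutrophils, chemokines and the interferon response. Spp1, which encodes the secreted phosphoprotein osteopontin, rose from 2.49 ± 1.38 to 1802 ± 1839 CPM (SD, n = 4; log2 fold change 8.54, SE 1.21), and Chil3, a chitinase-like protein of macrophages, from 1.08 to 511 CPM (8.29, SE 0.78). The neutrophil collagenase Mmp8 rose from 6 to 3149 reads over the 4 libraries and Slc7a11, the cystine-glutamate antiporter, from 9 to 2707. Ntrk3, the receptor of neurotrophin 3, fell from 555 ± 108 to 11.3 ± 6.76 CPM (-5.90, SE 0.45), and Car14, a membrane carbonic anhydrase, from 27.6 to 0.465 CPM (-6.03, SE 0.40). Slfn4 (7.39), Orm2 (7.24) and Fam110c (1036 reads against 5 in the 4 saline libraries) were higher too, as was the arginase Arg2, with 660 reads against 0 reads in KO saline. Fras1 (873 reads in saline and 9 after isoproterenol), Rab17 (286 and 4), Shisa7 (-5.72), Lctl (-5.16), the prostaglandin D synthase Ptgds (-5.14) and the interleukin 17 receptor gene Il17re (-5.13) were lower.

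All 44 nuclear-encoded respiratory chain genes fell in KO tissue (44 adjusted over the list alone, median -1.79, camera adjusted p = 2.17e-12), with adjusted p = 0.623 with an estimated correlation. The complex I subunit Ndufb8 fell by 2.11 and the complex II subunit Sdhb by 2.35. All 17 TCA cycle genes fell as well, led by Idh2 (-2.98) (17 adjusted over the list alone, median -2.24, camera adjusted p = 3.05e-06, adjusted p = 0.623 with an estimated correlation). Without KO isoproterenol replicate 1, 43 respiratory chain genes (median -1.28) and 15 TCA cycle genes (median -1.64) were lower. Lipogenesis genes had 12 of 23 lower and 0 higher (12 adjusted over the list alone, camera adjusted p = 0.00253, adjusted p = 0.623 with an estimated correlation), among them Thrsp (-3.83), the triglyceride synthase Dgat2 (-2.60) and the citrate lyase Acly (-2.28). Thermogenic genes had 16 of 29 lower and 2 higher (16 and 2 adjusted over the list alone, camera adjusted p = 0.0124, adjusted p = 0.765 with an estimated correlation), with Cox8b at -3.63 and Prdm16, a transcriptional regulator of brown fat identity, at -1.03. Without KO isoproterenol replicate 1, 16 were lower and 5 higher. Glycolysis genes had 14 of 22 lower and 3 higher, the insulin-responsive transporter Slc2a4 at -2.86 and the transporter Slc2a1 at 1.79 (14 and 3 adjusted over the list alone, camera adjusted p = 0.0145, adjusted p = 0.727 with an estimated correlation). Fatty acid oxidation genes had 15 of 32 lower and 2 higher, Cpt1a (2.54) and Fabp5 (2.16) (15 and 2 adjusted over the list alone, camera adjusted p = 0.0221, adjusted p = 0.780 with an estimated correlation). Of 22 genes of heat-producing cycles other than UCP1, 12 were lower, such as Pm20d1 (-4.66), and 2 higher, such as the phosphatase Alpl (1.81) (12 and 2 adjusted over the list alone, camera adjusted p = 0.0251, adjusted p = 0.727 with an estimated correlation). Scores of this list in KO saline replicates 1 to 4, at -0.15, 0.67, 0.55 and -0.29, moved with skeletal muscle scores of -2.92, 1.80, 1.83 and -4.00. The list is thus not free of muscle signal. In KO isoproterenol replicates 1 to 4 the scores were -1.97, -0.45, -0.26 and -0.21, with muscle at -3.72, 1.10, 1.10 and -1.80. Pan-adipocyte markers had 8 of 15 lower and 0 higher, Cebpa at -1.88 and Adipoq at -1.92 (8 adjusted over the list alone, camera adjusted p = 0.0101, adjusted p = 0.727 with an estimated correlation). Camera without KO isoproterenol replicate 1 no longer called the thermogenic programme (camera adjusted p = 0.0805), fatty acid oxidation (0.140, with 4 genes higher and 13 lower), heat-producing cycles (0.0657) or pan-adipocyte markers (0.0657). The thermogenic, fatty acid oxidation and pan-adipocyte falls were not shared by all 4 libraries. Scores of the thermogenic programme in KO isoproterenol replicates 1 to 4 were -3.49, -0.50, -0.18 and 0.94 (0.04 to 0.40 in KO saline). Those of fatty acid oxidation were -2.78, -0.94, -0.35 and 0.72 (0.18 to 0.34). Pan-adipocyte markers scored -2.04, -0.95, -0.24 and 0.24 (0.20 to 0.33). Replicate 4 was thus above KO saline in the first 2 lists and within its range in the last.

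Macrophage and neutrophil markers and chemokine and interferon genes rose in the same libraries, and lymphocyte markers did not rise as a list. Macrophage markers had 19 of 20 higher and 0 lower (19 adjusted over the list alone, median 2.54, camera adjusted p = 4.38e-09), Cd68 at 4.56 and Fcgr1 at 5.03. Interferon response genes had 27 of 28 higher and 0 lower (27 adjusted over the list alone, median 2.17, camera adjusted p = 1.62e-09), Irf7 at 3.35 and Oasl2 at 3.11. Inflammatory cytokines and chemokines had 19 of 23 higher and 1 lower (19 and 1 adjusted over the list alone, camera adjusted p = 7.78e-08), with the monocyte attractants Ccl2 at 5.67 and Ccl7 at 5.95. Extracellular matrix genes had 18 of 27 higher and 0 lower (19 adjusted over the list alone, camera adjusted p = 1.49e-06), Timp1 at 5.65 and the lysyl oxidase Lox at 1.85. Cell cycle genes had 22 of 28 higher (24 adjusted over the list alone, median 1.61, camera adjusted p = 1.49e-06), Mcm6 at 1.88 and E2f1 at 1.95. For these 5 lists, adjusted p = 0.623 with an estimated correlation. Neutrophil markers had 7 of 8 higher (8 adjusted over the list alone, median 5.08, camera adjusted p = 2.72e-06, adjusted p = 0.306 with an estimated correlation), S100a8 at 5.58. Lymphocyte markers had 1 of 15 higher and 4 lower (1 and 4 adjusted over the list alone, median -1.04, camera adjusted p = 0.263), and 1 higher and 7 lower without KO isoproterenol replicate 1 (median -1.67). Endoplasmic reticulum chaperones had 12 of 18 higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 7.20e-04, adjusted p = 0.623 with an estimated correlation), such as Manf (1.74) and Sdf2l1 (3.11). Proteasome genes had 12 of 28 higher and 1 lower (12 and 1 adjusted over the list alone, camera adjusted p = 0.00301, adjusted p = 0.727 with an estimated correlation).

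Over all genes, 7460 were called in KO tissue, 3647 higher and 3813 lower (limma, Benjamini-Hochberg), 2017 and 2173 of them by at least 2-fold. Fitted on the 8 KO libraries alone, 5178 genes were called, with 39 of 44 respiratory chain, 12 of 17 TCA cycle and 9 of 23 lipogenesis genes lower. In that fit the cell cycle count was 11 higher, the lymphocyte count 2 lower and 1 higher, and the thermogenic count 7 lower and 1 higher. The glycolysis count was 5 lower and 2 higher, the fatty acid oxidation count 7 lower and 2 higher, the heat-producing cycles count 7 lower and 2 higher, the pan-adipocyte count 4 lower and the proteasome count 5 higher and 1 lower. Library totals, which moved the median of all genes by 0.18, gave 4493 higher and 2939 lower.

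**Figure D2:**
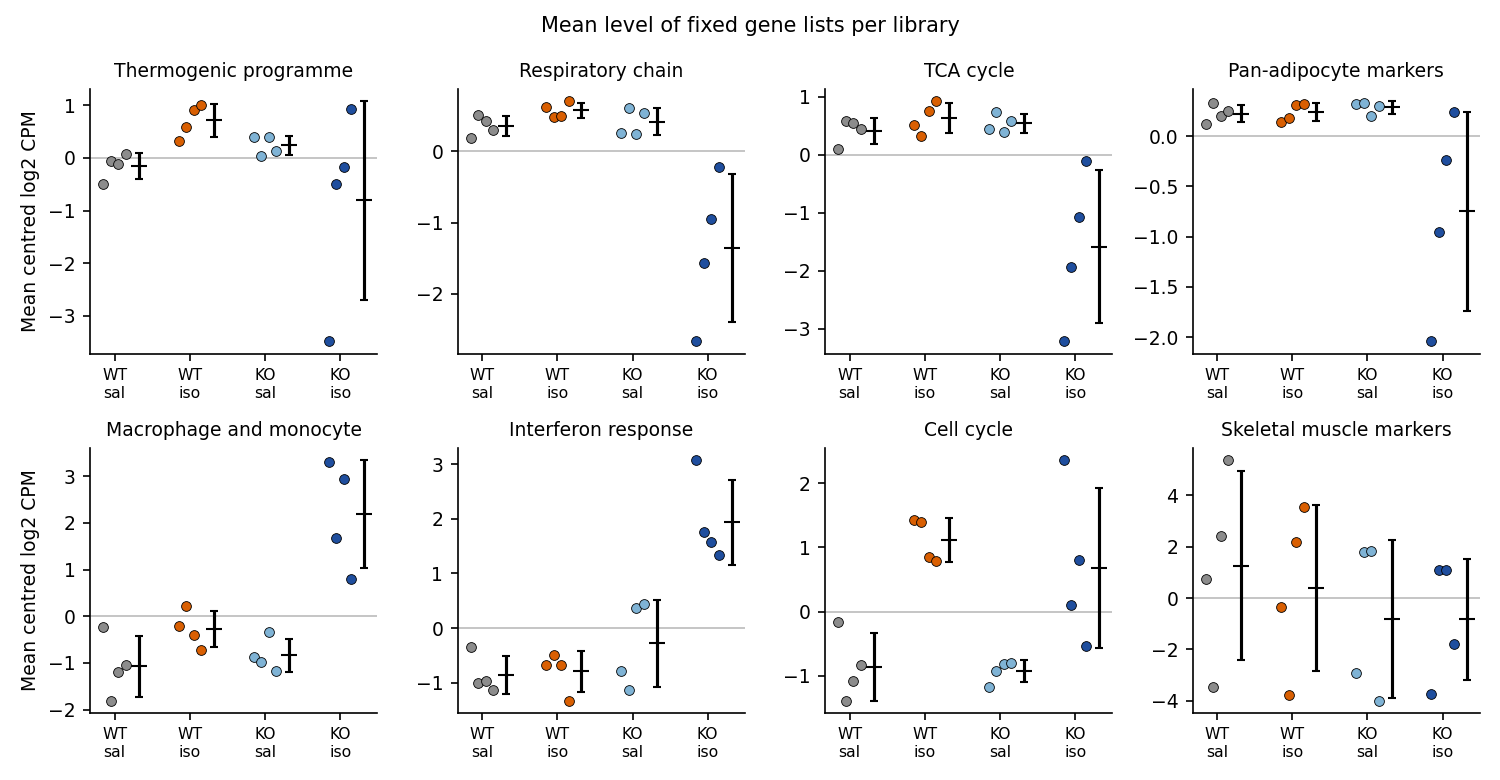
Scores of 8 fixed gene lists per library (vertical axes, mean log2 CPM of the members after centring each gene over the 16 libraries), 1 point per library, with the mean and SD of each group of 4. The 4 KO isoproterenol libraries have the lowest respiratory chain scores and the highest interferon scores of the 16.

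Under saline, few genes were called between KO and WT tissue in the fit of all 16 libraries. Rnf150, a ubiquitin ligase gene on chromosome 8, was lower in KO, at a mean of 7.63 against 51.9 CPM (n = 4; log2 fold change -2.79, SE 0.35, limma adjusted p = 0.00509). Nceh1, a hydrolase of cholesterol esters, was higher at 39.3 ± 3.37 against 9.51 ± 1.66 CPM (2.06, SE 0.27, limma adjusted p = 0.00541), and Mthfd2, a mitochondrial enzyme of folate metabolism, at 14.1 against 3.32 CPM (2.03, SE 0.34, limma adjusted p = 0.0328). Also higher in KO were Wwc1 (2.68), Nabp1 (1.63), the RNA-binding protein gene Igf2bp2 (1.43), Zkscan3 (1.12) and the RNA helicase gene Ddx39 (0.97). Also lower were Mri1 (-0.83) and the calcium-binding protein gene Sri (-0.73).

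In all, 15 genes were called under saline, 11 higher and 4 lower (limma, Benjamini-Hochberg), while 1061 had an unadjusted p under 0.05. The other 5 were Aldh1b1 (2.46), named after its value was seen, and 4 predicted or pseudogene-type loci whose reads other genes may share. No member of the thermogenic programme, the respiratory chain or the TCA cycle was called, over all genes or adjusted over the list alone, with medians of 0.20, 0.10 and 0.12, and 5, 0 and 0 of their genes had an unadjusted p under 0.05 in limma's test. Integrated stress response genes had 1 of 25 higher, Mthfd2 (2 adjusted over the list alone, median 0.53, camera adjusted p = 5.94e-05, adjusted p = 0.531 with an estimated correlation). Scores of that list were -0.15 to 0.13 in KO saline and -0.60 to -0.39 in WT saline, without overlap. Interferon genes had 0 of 28 called by limma, 3 with an unadjusted p under 0.05 (0 adjusted over the list alone, median 0.55, camera adjusted p = 2.01e-05, adjusted p = 0.850 with an estimated correlation). KO saline replicates 3 and 4 scored 0.36 and 0.44 on this list, while replicates 1 and 2, at -0.79 and -1.13, lay within the range of WT saline (-1.13 to -0.35). Camera also called the proteasome (median 0.13, camera adjusted p = 8.52e-05), glycolysis (0.28, 0.00363), skeletal muscle (-2.28, 0.00235) and smooth muscle markers (-0.15, 0.0256), each with 0 members called over all genes and adjusted p = 0.850 with an estimated correlation. Glycolysis had 1 member higher and smooth muscle 1 lower adjusted over the list alone, and the other pair of lists 0. Skeletal muscle scores overlapped widely, at -4.00 to 1.83 in KO saline and -3.46 to 5.37 in WT saline. Rnf150 and Nceh1 were called in every alternative run, while the calls of the 8 other genes named by rule ended in 2 (Zkscan3) to 13 (Mri1) of them. The count of 15 was 50 when the 8 saline libraries were fitted alone. Among them 1 thermogenic gene, the targeted gene Ucp1, was lower and 1 glycolysis gene higher. The count in the fit of all groups was 8, 4, 7 and 5 without WT saline replicates 1 to 4, and 5, 11, 5 and 5 without KO saline replicates 1 to 4.

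After isoproterenol, respiratory chain, TCA cycle and lipogenesis genes were lower in KO than in WT tissue, and interferon, chemokine and macrophage genes were higher. Slc7a11 was at 38.4 ± 41.2 CPM in KO and 0.205 ± 0.182 CPM in WT (SD, n = 4; 2707 against 8 reads, a fitted log2 fold change of 7.57, SE 0.89, that depends on the prior count), and Spp1 at 1802 against 9.45 CPM (7.25, SE 1.21). Car14 was lower in KO, at 0.465 ± 0.249 against 66.5 ± 25.4 CPM (-7.29, SE 0.40), as were the lipoprotein-bound esterase Pon1, at 4.29 against 178 CPM (-5.38, SE 0.36), and Tfr2, at 1.51 against 49.0 CPM (-5.18, SE 0.43). Slfn4 (6.58), Rgs1 (6.53), the interleukin 7 receptor Il7r (6.03) and Ms4a4c (6.08) were higher in KO. Rhov had 748 reads in KO against 2 in WT, and Sprr1a 349 against 1. Ptgds (-5.81), Fcrls (-5.21), Aspg (22.7 against 420 CPM) and the fructose transporter Slc2a5 (-4.71) were lower.

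All 44 respiratory chain genes were lower in KO than in WT tissue under isoproterenol (44 adjusted over the list alone, median -1.93, camera adjusted p = 1.01e-15), as were all 17 TCA cycle genes (17 adjusted over the list alone, median -2.20, camera adjusted p = 3.11e-07). Interferon genes had 27 of 28 higher (27 adjusted over the list alone, median 2.78, camera adjusted p = 2.88e-13), Irf7 at 4.55 and Mx1 at 5.34, and cytokines and chemokines 20 of 23 higher and 1 lower (20 and 1 adjusted over the list alone, camera adjusted p = 1.48e-08), Cxcl10 at 5.72. Macrophage markers had 16 of 20 higher and 0 lower (18 adjusted over the list alone, median 2.19, camera adjusted p = 2.09e-07). Lipogenesis genes had 14 of 23 lower and 1 higher (17 and 1 adjusted over the list alone, camera adjusted p = 1.96e-05), the fatty acid synthase Fasn at -3.76. Integrated stress response genes had 12 of 25 higher and 2 lower (12 and 2 adjusted over the list alone, camera adjusted p = 0.00664), Atf3 at 5.21 and the stress cytokine Gdf15 at 5.73. For these 7 lists, adjusted p = 0.581 with an estimated correlation. Thermogenic genes had 16 of 29 lower and 0 higher (17 adjusted over the list alone, camera adjusted p = 0.00109, adjusted p = 0.793 with an estimated correlation), Esrra at -1.86 and Cox7a1 at -3.65, with 14 lower and 3 higher without KO isoproterenol replicate 1, 10 lower without WT isoproterenol replicate 3 or 4, and 6 lower when the 8 libraries were fitted alone. Cell cycle genes had 1 of 28 higher, Pcna at 1.16, and 0 lower (1 adjusted over the list alone, median -0.70, camera adjusted p = 0.486). Without KO isoproterenol replicate 1, 18 cell cycle genes were lower and 1 higher (median -1.36, camera adjusted p = 0.00320).

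In all, 6853 genes differed between KO and WT under isoproterenol, 3311 higher and 3542 lower (limma, Benjamini-Hochberg), 1638 and 2050 by at least 2-fold. Library totals, which moved the median of all genes by 0.26, gave 5030 higher and 2527 lower.

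The isoproterenol response itself differed between the genotypes for 3787 genes, 1674 with a higher and 2113 with a lower response in KO (limma, Benjamini-Hochberg test of the interaction). Car14 had the largest lower difference of the named genes, with 26.1 to 66.5 CPM in WT against 27.6 to 0.465 CPM in KO (interaction -7.37, SE 0.56, limma adjusted p = 9.01e-06). Tfr2 (-5.96), Ptgds (-6.17), Slc2a5 (-7.18), Pon1 (-5.36), Fcrls (-5.35) and Ttc25 (-4.88) had lower responses in KO too. Slc7a11 (8.44, SE 1.25, limma adjusted p = 9.05e-04), Serpina3m (7.29), the arginase Arg1 (6.68), Slfn4 (6.41), Lncenc1 (6.12) and AU022793 (5.87) had higher responses. Of these, all but Slfn4 had a mean of at most 3 reads per library in at least 1 group, so their fitted values depend on the prior count. Elovl3 had a lower response (-5.02, SE 1.76, limma adjusted p = 0.0492), with KO saline at 49.7 ± 40.7 CPM and KO isoproterenol at 615 ± 749 CPM, a call that 20 of the alternative settings ended, most of them by leaving out 1 library. The WT replicate block was among them (adjusted p = 0.0756). Of the 3787 genes, 1356 were higher after isoproterenol in KO and not called in WT, and 1504 were lower in KO and not called in WT. Another 228 were higher and 140 lower in WT and not called in KO, 100 were higher in WT and lower in KO, and 42 the reverse.

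Respiratory chain genes had a lower response in KO for 43 of 44 (44 adjusted over the list alone, median -2.02, camera adjusted p = 1.07e-16) and TCA cycle genes for 15 of 17 (17 adjusted over the list alone, median -2.30, camera adjusted p = 1.30e-07). Lipogenesis genes did for 11 of 23 with 0 higher (14 and 1 adjusted over the list alone, camera adjusted p = 7.27e-06), Fasn at -4.65, and glycolysis genes for 12 of 22 with 1 higher, Slc2a1 at 2.40 (16 and 1 adjusted over the list alone, camera adjusted p = 1.64e-05). Higher responses were called for 22 of 28 interferon genes (26 adjusted over the list alone, camera adjusted p = 9.41e-10), 16 of 23 cytokines and chemokines (17 adjusted over the list alone, camera adjusted p = 1.31e-07) and 10 of 20 macrophage markers (12 adjusted over the list alone, camera adjusted p = 2.38e-06). For these 7 lists, adjusted p = 0.586 with an estimated correlation. Thermogenic genes had a lower response for 8 of 29 (9 adjusted over the list alone, camera adjusted p = 6.11e-05) and fatty acid oxidation genes for 13 of 32 with 1 higher, Cpt1a at 2.09 (16 and 1 adjusted over the list alone, camera adjusted p = 1.59e-04), and for both lists adjusted p = 0.700 with an estimated correlation. Without WT isoproterenol replicate 4, 13 interferon, 9 TCA cycle and 7 fatty acid oxidation genes were called, and without WT saline replicate 1, 14, 9 and 7. Without KO saline replicate 1 or 2, 14 interferon genes were called, and without WT isoproterenol replicate 3 or KO saline replicate 2 or 4, 8 fatty acid oxidation genes. Without KO isoproterenol replicate 4, 16 macrophage, 17 lipogenesis, 22 fatty acid oxidation and 19 thermogenic genes were called. With the WT replicate block 8 TCA cycle and 4 fatty acid oxidation genes had a lower response. Most called respiratory chain, interferon and macrophage genes kept their call with that block. Others lost it, such as Atp5b (limma adjusted p = 0.0859), Mx2 (0.0844) and Adgre1 (0.0888). Cell cycle genes had 1 of 28 called, Pcna at 1.10 (adjusted p = 0.0792 with the WT replicate block; 0 adjusted over the list alone, camera adjusted p = 0.768, and 0.0162 without KO isoproterenol replicate 1). Library totals, which moved the median by 0.29, gave 2895 higher and 1477 lower.

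Across the 15350 genes, which are not independent replicates, the isoproterenol log2 fold changes of WT and KO had a Pearson correlation of 0.415 and a Spearman correlation of 0.357. Genes called in both genotypes numbered 1554, of which 1412 moved in the same direction. Both rose for 553 genes, where independent lists of these sizes would share 277, and both fell for 859, where they would share 343. Genes higher in WT and lower in KO numbered 100 against 290 for independent lists, and those lower in WT and higher in KO 42 against 328. The SD of the log2 fold changes was 0.753 in WT and 1.26 in KO.

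**Figure D3:**
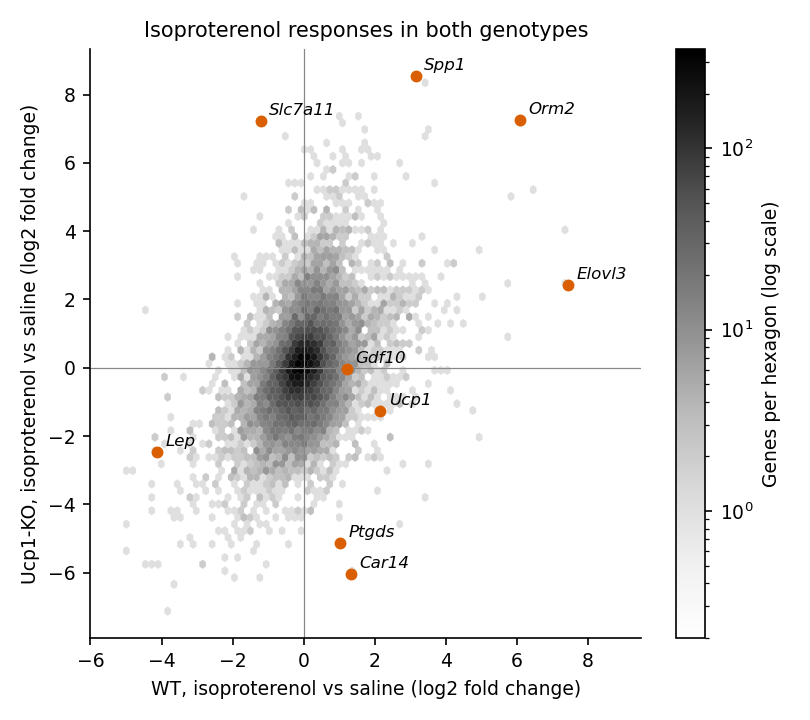
Log2 fold changes after isoproterenol in WT (horizontal axis) and KO (vertical axis) for the 15350 genes, shaded by the number of genes per hexagon on a log scale, with 9 named genes in orange. Across all genes the Pearson correlation is 0.415, and Orm2 rose and Lep fell in both genotypes, and Car14 rose by 1.34 in WT and fell by 6.03 in KO.

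Gdf10 (ENSMUSG00000021943), whose product BMP3b the series title names as a factor released by fat, was at 12.2 ± 4.25 CPM in WT saline and 27.6 ± 5.59 CPM in WT isoproterenol (SD, n = 4). In KO it was at 10.6 ± 1.63 CPM under saline and 12.6 ± 9.38 CPM under isoproterenol, where replicates 1 to 4 held 25.8, 7.20, 12.8 and 4.74 CPM. Gdf10 rose in WT after isoproterenol (log2 fold change 1.23, SE 0.40, limma adjusted p = 0.0459) and was at -0.03 in KO (limma adjusted p = 0.957). Under isoproterenol it was lower in KO than in WT (-1.40, SE 0.40, limma adjusted p = 0.00974), and under saline the difference was -0.15 (limma adjusted p = 0.991). BMP and TGF-beta genes, a fixed list with Gdf10 in it, had 3 of 43 higher and 4 lower in WT (3 and 4 adjusted over the list alone, camera adjusted p = 0.769, and 1 higher and 4 lower with the WT replicate block). In KO 13 were higher and 2 lower (13 and 1 adjusted over the list alone, camera adjusted p = 0.0195, adjusted p = 0.623 with an estimated correlation), Gdf15 at 5.89. Secreted factors of brown fat, another list with Gdf10, had 15 of 42 higher and 10 lower with the 8 WT libraries fitted alone. With the 8 KO libraries fitted alone, 9 were higher and 14 lower. The difference of the Gdf10 responses was not called (interaction -1.26, SE 0.56, limma adjusted p = 0.111). In the exact permutation test the WT response had p = 0.0286, the smallest 4 against 4 libraries can give (adjusted p = 0.0571), with all 4 isoproterenol libraries above all 4 saline libraries. KO against WT under isoproterenol had an exact permutation p of 0.0857 (adjusted p = 0.137). The WT call ended in 7 of the 8 fits that left out 1 of its libraries (log2 fold change 1.03 to 1.42, limma adjusted p 0.0436 to 0.136), with voom weights (adjusted p = 0.0545), with library totals (adjusted p = 0.0800) and with the WT replicate number as a block (adjusted p = 0.0773). Fitted on the 8 WT libraries with that block it was called (limma adjusted p = 0.00170). The difference under isoproterenol was not called when its 8 libraries were fitted alone (adjusted p = 0.0518). Without KO isoproterenol replicate 1 the interaction was called at -1.70 (limma adjusted p = 0.00963).

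**Figure D4:**
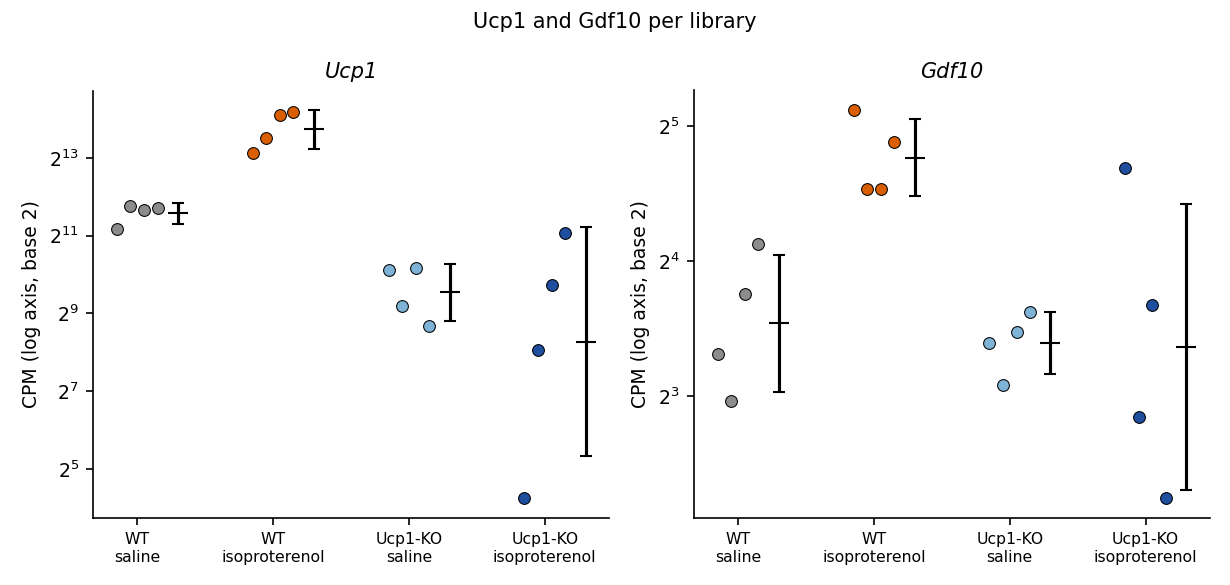
Ucp1 and Gdf10 per library in CPM (vertical axes), 1 point per library on a log axis, with the mean and SD of log2 CPM of each group of 4. The 4 WT isoproterenol libraries have the highest Ucp1 levels of the 16, at 8905 to 18458 CPM, and Gdf10 in KO isoproterenol spreads from 4.74 to 25.8 CPM.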

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

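Of the tests in this part, those of single libraries, scaling, adipocyte share, placement on the chromosome and muscle were chosen after the result was seen; so were the random signs for the interaction and the limit to splits that part the WT pairs. The other splits of libraries and the test of DNA around Ucp1 were written before.

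The isoproterenol response differed between KO and WT for 3787 genes, 24.7% of all genes, in the interaction test. Of the genes named by the size of their fold change in the 2 isoproterenol responses or the interaction, 27 were among them (KO response minus WT response, log2). The 8 higher and 8 lower genes named for the interaction are in this set by selection, since a call was required. Higher responses in KO were those of Slc7a11 (8.44), Serpina3m (7.29), Arg1 (6.68), Rhov (6.49), Slfn4 (6.41), Lncenc1 (6.12), Sprr1a (6.07), AU022793 (5.87), Mmp8 (5.82), Spp1 (5.39), Arg2 (5.21), Chil3 (4.96) and Fam110c (3.56). All of these but Slfn4, Spp1 and Chil3, and Fras1 and Rab17 below, had a mean of at most 3 reads per library in at least 1 of the 4 groups (Sprr1a 0 reads in both saline groups, Arg2 0 in KO saline), and their fitted values depend on the prior count. Lower responses were those of Car14 (-7.37), Slc2a5 (-7.18), Ptgds (-6.17), Tfr2 (-5.96), Pon1 (-5.36), Fcrls (-5.35), Elovl3 (-5.02), Ttc25 (-4.88), Ntrk3 (-3.60), Fras1 (-3.29), Hist1h1d (-2.96), Rab17 (-2.60), Il17re (-2.58) and Lctl (-1.99).

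Camera called 16 lists in the interaction, none of them with an estimated correlation. Median differences were -2.30 for the TCA cycle, -2.10 for fatty acid oxidation, -2.02 for the respiratory chain, -1.85 for lipogenesis, -1.83 for the thermogenic programme, -1.62 for glycolysis, -1.34 for haemoglobin, -1.15 for UCP1-independent heat cycles and -1.12 for pan-adipocyte markers. They were 2.85 for neutrophil markers, 2.68 for cytokines and chemokines, 2.05 for the interferon response, 1.99 for macrophage markers, 0.69 for extracellular matrix, 0.62 for endoplasmic reticulum chaperones and 0.32 for BMP and TGF-beta genes. Scores of the heat cycles ran in the same order over the replicates as skeletal muscle scores in WT saline and in WT isoproterenol, so that list carries muscle signal. Medians without KO isoproterenol replicate 1 were -1.03 for the thermogenic programme, -1.34 for fatty acid oxidation, -0.60 for pan-adipocyte markers, 0.34 for extracellular matrix and 0.37 for chaperones, each more than 1.5 times nearer 0. The interaction was also fitted with the effects of genotype and treatment kept and the deviations of each library from its group mean given a random sign, which leaves no interaction. Of 100 such fits with the real one included, 1 gave as many as 3787 genes, the real one, and the highest other gave 322. Chance was thus excluded for the count at the 0.05 level under signs drawn independently for each library, which do not keep the WT pairs. The 35 splits of 8 libraries gave the real count 1 time each for 3 comparisons. Fitted on 8 libraries, these real counts were 5178 for KO isoproterenol (highest other 21), 50 under saline (5) and 4639 for KO against WT under isoproterenol (0). Each thus passed the 0.05 level, at the smallest share that 35 splits can give and without adjustment over the comparisons. For WT isoproterenol, where the numbers were taken to pair the libraries, the 8 splits that part all 4 pairs are too few for a share under 0.05, with 4923 genes for the real split and 0 for the highest other.

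The fall of respiratory chain genes in KO after isoproterenol was weighed first. A single library is argued against as the whole cause, since 43 of 44 genes were lower without KO isoproterenol replicate 1. The fall does not depend on the choice of the deposited factors over library totals, since 43 were lower with totals. Totals moved the median of all genes by 0.18 in KO, against a respiratory chain median of -1.79. That shift is too small to decide on a larger scaling error. A lower share of adipocytes was taken to lower adipocyte markers at least as far, so that the respiratory minus pan-adipocyte score would not fall. The score fell by 0.73 in KO (0.13 ± 0.16 to -0.60 ± 0.11, SD, n = 4, exact permutation p = 0.0286, the smallest possible). Adipocyte markers moved unevenly, however. Their median was -0.92 against -1.79 for the respiratory chain, while Adipoq, Cebpa and Slc2a4 fell further than the respiratory chain median. A score over the whole list therefore cannot decide on the share of adipocytes. Macrophage markers rose in the same libraries, and a change within adipocytes and a change of other cell types may both contribute, which these tests leave open. A response of KO tissue to isoproterenol remains a hypothesis.

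Genes called in KO saline near Ucp1 on chromosome 8 were weighed next. Rnf150, Ddx39 and Mri1 are 3 of the 15 called genes and lie within 50 tested genes of Ucp1, where 0.0977 were due by chance (1-sided exact hypergeometric test, p = 1.15e-04). DNA of another strain carried along with the targeted gene could give such a cluster. The correlation of KO differences under saline and isoproterenol over those 100 genes was 0.359, at the 89.5th percentile of 13134 windows (median 0.143). This lies between the bounds set for and against flanking DNA, which the test leaves open. An effect of the deletion on its neighbours could also show under both treatments. This correlation cannot separate the 2, and that effect was not tested. Under saline 23% of the 100 genes had an unadjusted p under 0.05 in limma's test, against 6.91% of all genes. Under isoproterenol Rnf150 (-1.26), Ddx39 (0.91) and Mri1 (-0.73) were called in the same directions, in a contrast where 44.6% of all genes were called. Among other neighbours with an unadjusted p under 0.05 under saline, Usp38, Tbc1d9 and Scoc were also called in the same direction. Gipc1, Asf1b, Cacna1a, Gm16183 and Nacc1 had the opposite sign under isoproterenol and were not called.

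Skeletal muscle markers spread widely in all 4 groups and were weighed last. The range of Acta1 within a group was 7.09 to 10.6 on the log2 scale and that of Ckm 8.31 to 10.4. Deviations of the markers from their group means had a median pairwise correlation of 0.944, which is consistent with muscle taken up in the dissected tissue. Treatment or genotype is argued against as the main cause, since 9.60% of the variance of the muscle score lay between groups.

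A single library lay far from the 3 others of its group in 20 of 352 groups tested (5.68%), where chance marks about 1 in 20 (17.6 expected). Of these, 10 were in WT saline, 4 in WT isoproterenol, 3 in KO saline and 3 in KO isoproterenol. Among list scores they were UCP1-independent heat cycles in KO isoproterenol replicate 1 (-1.97), endoplasmic reticulum chaperones in WT saline replicate 1 (-0.26), heat shock genes in KO saline replicate 2 (-0.35), cholesterol synthesis in WT isoproterenol replicate 4 (0.84), secreted factors in WT isoproterenol replicate 1 (0.33) and the circadian clock in WT saline replicate 1 (-0.0458). In WT saline the log2 CPM values were Arg2 (-2.92), Rhov (-2.92), Fam110c (-2.18) and Il7r (2.10) in replicate 1, Orm2 (-4.47) in replicate 2, Hist1h1d (-4.43) in replicate 3, and Pla2g2e (-4.59) and Mri1 (4.23) in replicate 4. In WT isoproterenol they were Mmp8 (-1.16) and Ttc25 (3.16) in replicate 2. In KO they were Strip2 (5.14) in saline replicate 2, Mthfd2 (4.65) in saline replicate 4, Fras1 (-5.26) in isoproterenol replicate 3 and Sprr1a (3.83) in isoproterenol replicate 2. The values of Arg2, Rhov, Fam110c, Orm2, Hist1h1d and Pla2g2e in WT saline and of Fras1 lay under the floor of 3 reads. Their distance from the other libraries therefore depends on the prior count and on counting error.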

How the results depend on the processing

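Library totals, 1 variance weight per group, the muscle covariate, centring over GC content and length, the block by header numbers, the block in WT alone and the list tests without KO isoproterenol replicate 1 were chosen after seeing the data. The count of genes changed by isoproterenol in WT was 5152 with group weights and 4923 with the 8 WT libraries alone, and 1623 to 2035 with 1 library left out. The count under saline was 77, 50 and 4 to 11 in the same fits. The weights were 1.72, 1.39 and 1.19 for WT saline, WT isoproterenol and KO saline and 0.350 for KO isoproterenol, so the wider spread of that group enters every contrast of the shared fit. Left-out libraries gave 6650 to 8313 genes for KO isoproterenol, 5781 to 7709 for KO against WT under isoproterenol and 2618 to 5666 for the interaction, and a correlation of the responses of 0.358 to 0.469. The Ucp1 difference of 2.16 in WT was called with group weights (adjusted p = 0.00472) and with 2 groups alone (1.18e-04), that of -2.02 under saline with 2 groups alone (0.0438) and the interaction of -3.43 with group weights (0.0217). With 1 library left out it was -2.20 to 0.0717 in KO and -4.36 to -2.09 in the interaction, where the change of sign or call came with KO isoproterenol replicate 1 or 4. The Gdf10 response in WT was not called with voom weights (1.21, adjusted p = 0.0545), library totals (1.11, 0.0800) or the muscle covariate (1.24, 0.0550), and was 1.03 to 1.42 with 1 library left out. Its difference of -1.40 under isoproterenol was not called with 2 groups alone (0.0518), and its interaction was -1.70 to -0.88 with 1 library left out. Lists called by camera numbered 8 in WT, 19 in KO, 6 under saline, 17 under isoproterenol and 16 in the interaction, and 0 in each with an estimated correlation. With fry they numbered 2 in WT and 0 under saline. Called lists without KO isoproterenol replicate 1 numbered 12, 15, 11, 15 and 18 in that order, with the thermogenic programme, heat cycles, fatty acid oxidation and pan-adipocyte markers lost in KO and heat cycles, extracellular matrix and pan-adipocyte markers lost and cell cycle gained under isoproterenol. Of 1725 comparisons of the other genes named by the size of their fold change, 1623 kept their call, 102 lost it and 0 reversed. Members named from the fixed lists alone were not in this count. Apart from fewer libraries in the left-out fits and the weights, the cause was not tested. Replicate numbers were taken to pair WT saline with WT isoproterenol (4 correlations of 0.21 to 0.54), where 6 of 8 libraries correlated best with their own number, and no other 2 groups (-0.43 to 0.39). With the number as a block in WT alone the WT count was 1865 (1936 with GC content and length centred, 5297 on the 8 WT libraries), 8 lists were called, Ucp1 in WT was called on the 8 libraries (4.84e-05), and Gdf10 (1.23, adjusted p = 0.0773, or 1.32 and 0.0550 with GC content and length centred) and Cpne5 were not called in the shared fit. For the interaction the block in WT alone gave 2650 genes (2692 with GC content and length centred) and 16 lists, and Elovl3 was not called. In these 2 contrasts no other call of a list or of a gene named by the size of its fold change changed with that block in the shared fit. Some list members named for these contrasts lost their call, among them Mrc1, Cd68, C1qc, Lpl and Hmox1 in WT and Pcna in the interaction. With the number as a block in all groups the counts were 2276, 7315, 11, 6683 and 3718, and by header numbers 2607, 7550, 11, 6933 and 4070. The recovered reads would have allowed a count-based test, which was not run, and voom weights from those reads were used instead. No comparison without a filter was possible because genes had been left out before deposit. Depth limits genes of a few reads per library.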

Other observations

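No test in this part was added to those described before; the gene lists were fixed in advance. Circadian clock genes had 6 of 17 lower and 4 higher in KO after isoproterenol (7 and 4 adjusted over the list alone, camera adjusted p = 0.290; 5 lower and 2 higher with the 8 KO libraries fitted alone). Hlf (-3.18), Dbp (-2.54), Per3 (-1.94) and Tef (-1.51), output or core genes of the clock, fell in KO, and in WT none of these 4 was called. The responses differed for 4 of the 17 genes, all lower in KO, among them Hlf (interaction -2.75, SE 0.48, limma adjusted p = 0.00215), Per3 (-1.96) and Ciart (-1.97).

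Among genes of the antioxidant response, 9 of 21 rose and 7 fell in KO (10 and 7 adjusted over the list alone, camera adjusted p = 0.429; 7 and 4 with the 8 KO libraries fitted alone). The haem oxygenase Hmox1 rose by 5.04 in KO and 1.01 in WT on the log2 scale (WT limma adjusted p = 0.0392, and 0.0623 with the WT replicate block; interaction 4.03, SE 0.44, limma adjusted p = 1.09e-04), while the secreted peroxidase Gpx3 fell by 3.50 in KO and by 2.50 in WT. Among secreted factors, S100b rose by 2.03 in WT and fell by 2.71 in KO (interaction -4.75, SE 0.47, limma adjusted p = 4.56e-05), and endothelin Edn1 rose in both, by 2.99 and 2.58. Haemoglobin genes had 5 of 5 lower in KO after isoproterenol (5 adjusted over the list alone, camera adjusted p = 0.00329, adjusted p = 0.623 with an estimated correlation), and 0 of 5 called in WT.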
